A study of Homo sapiens with 6 samples.

How the data were processed

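Total RNA from ED-40515 cells was labelled with Cy3 and hybridised to single-colour Agilent arrays, 3 samples with DMSO and 3 with 1 µM TAS-116, for 16 h, per the labels. Spot intensities were extracted with Agilent Feature Extraction, named in the submitters' processing notes, in version 10.7.3.1 per the file headers. The authors deposited 1 scanner file per array, with the processed intensity (background subtracted and detrended within the array, per the file headers), the raw mean intensity and local background intensity of each spot, and flags for spots well above background, saturated or outlying. They also deposited a table of log2 values, which per the labels are log2 ratios of the normalized signal to the median of the DMSO samples. How signals were normalized between arrays is not named in the labels. How the deposited log2 values relate to the scanner files was checked. They followed the log2 processed signal minus the array's 75th percentile and minus the DMSO median, with Pearson correlations across probes of 0.999986 or more per array among probes well above background. Scale, centring and direction are thereby known. The medians of the deposited log2 values were 0, -0.020 and 0 for DMSO replicates 1 to 3 and -0.31, -0.26 and 0.30 for TAS-116 replicates 1 to 3.

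Each array held 62976 spots, of which 61657 were not controls. Control spots were left out, as were 2940 spots of ERCC spike-in probes, of which 77 to 78 per DMSO array and 83, 63 and 40 on the TAS-116 arrays were well above background. The remaining 50599 probes were named through their RefSeq accession, without versions, in a table of GRCh38.p14 genes, which matched 28174 probes, and otherwise kept the name in the files, giving 36332 gene names. Probe coordinates are those of the array files on hg19. Values were log2 of the processed intensity minus the array's 75th percentile over these probes. Spots flagged as outliers were left out, spots of a probe were averaged, and the probe with the highest mean over the 6 arrays stood for its gene. A gene was kept if that probe was well above background on all 3 arrays of at least 1 group, which left 16108 genes. Of these, 3855 had over 1 kept probe, and for 122 of them probes past the threshold went both ways. The 75th percentile of the processed intensity was 417 to 503. The raw local background had a median of 122 on the array of TAS-116 replicate 3 and of 45 to 49 on the others.

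Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the term) with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Tables were handled with data.table (version 1.17.8). Positive fold changes are higher in TAS-116. The exact permutation p of 3 samples against 3 cannot go below 0.1, so no test of single values was made. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least", the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Setting such genes at their bound did not change the printed median of any of the 5 lists that hold one.

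Gene lists were tested with limma's camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 30 lists, each with at least 3 kept genes, and with fry and camera with an estimated correlation beside it. The lists covered cytosolic heat shock, chaperonin and mitochondrial chaperones, proteasome, unfolded protein and metabolic stress responses, the cell cycle, p53 and cell death, T-cell and leukemia genes, signaling targets, MYC, ribosomes, metabolism, interferon, antigen presentation, autophagy, histones, actin and serum response factor targets, and markers of B cells, myeloid cells, natural killer cells, and epithelium and fibroblasts. Lists, designs, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 6 largest rises and 6 largest falls among genes past the threshold with a proper gene name, well above background on all 6 arrays, not saturated and with groups that did not overlap. From each list it took up to 3 members past the threshold with the largest change, or the 2 with the smallest p where fewer than 2 passed, and always HSP90AA1, HSP90AB1, HSP90B1, TRAP1 and HSF1. It named 102 genes, not all of which are printed.

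On simulated data with the real genes' means and spreads, 200 of 16108 genes changed by known amounts. The comparison of TAS-116 with DMSO recovered 98.5% of genes changed by 2 on the log2 scale, 89.6% of those changed by 1 and 53.7% of those changed by 0.5, and 5.85% of the calls were false. Without any change limma called 0 genes, with 859 at an unadjusted p under 0.05. The simulated genes varied independently of each other and without a slide effect. Far fewer of them changed than the 9037 genes that passed in the real comparison. These shares therefore need not hold for the real data. In all, 23 alternatives were run, covering the scaling, background correction, the deposited log2 values, the filter on dim probes, saturation, the probes of a gene, the variance model, slide, the replicate number as a block, the threshold, the correlation in camera and each sample left out. Of these, 2 scalings were added after seeing the data, the percentile over detected probes and Agilent's E1A spike-in controls. The probe of a gene and the filter were kept when samples were left out, and with slide as a random block camera ranked the moderated statistics.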

Results

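Genome-wide expression was measured in ED-40515, a cell line derived from adult T-cell leukemia (ATL), a malignancy of mature CD4-positive T cells caused by the retrovirus HTLV-1. The cells received either the solvent DMSO or 1 µM TAS-116 (pimitespib), an orally available inhibitor of the cytosolic chaperone HSP90 in its alpha and beta forms, for 16 h. Each group had 3 samples, and each sample was hybridised to 1 single-colour Agilent array. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Between 41.0% and 46.0% of the gene probes lay well above background on an array, and no probe was saturated. For arrays, the number of samples limits the precision. Over the 15114 genes well above background on all 6 arrays, Pearson correlations across genes were 0.997 to 0.998 between arrays of a group and 0.978 to 0.980 between arrays of different groups, with genes not being independent replicates. All 3 DMSO arrays and TAS-116 replicate 1 lay on slide 1, and TAS-116 replicates 2 and 3 lay on slide 2. The fit with slide as a block and the fit within slide 1 give the same fold change for a gene, and this value is printed as the value within slide 1.

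The comparison asked which genes changed with TAS-116 in these leukemia cells. After 16 h, heat shock genes and interferon-response genes were higher, and DNA replication genes and MYC-dependent ribosome biogenesis genes were lower. By camera these list calls passed with a preset correlation, and with an estimated one they did not (adjusted p = 0.23 each with an estimated correlation), except under 1 or both of 2 other scalings. HSPA1A, the main heat-inducible HSP70, rose 4.59-fold, and ISG20, an interferon-induced exonuclease, rose 4.40-fold. CCNE2, the cyclin E2 of the G1 to S transition, was 12.5-fold lower, and MYC, the growth-promoting transcription factor, was 6.32-fold lower. In all, 4244 of 16108 genes were higher and 4793 were lower in TAS-116 than in DMSO by limma at an adjusted p under 0.05. Of these, 552 were higher and 757 lower by at least 2-fold. With slide as a block the counts were 2827 higher and 3410 lower, and within slide 1 they were 2464 and 3116. As a random block, slide gave 4668 higher and 5167 lower genes. The correlation between arrays of a slide was -0.17 in that fit, so arrays of a slide were not more alike. These counts, and calls named below with slide as a random block, thus do not show that calls survive a correction for slide. Scaling each array to the probes detected on all arrays, an alternative chosen after seeing the data, moved the median log2 fold change of all genes from -0.014 to 0.11. It raised the share of higher genes among those changed from 47.0% to 61.7%, while quantile normalization gave 54.8%, median scaling 40.0% and E1A scaling 38.7%, so the balance of rises and falls depends on the scaling.

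Of 30 gene lists, 5 shifted relative to the other genes by camera. Heat shock genes, interferon-response genes and T-cell genes were higher, and replication genes and MYC and ribosome biogenesis genes were lower. With the 75th percentile scaling, none of the 5 calls held when camera estimated the correlation between genes from these 6 arrays, where all 5 had an unadjusted p under 0.05 and each had an adjusted p = 0.23 with an estimated correlation. For the T-cell list the estimated correlation was -0.022, below the preset 0.01. Its unadjusted camera p still rose from 0.0040 to 0.038, so correlation between genes alone does not account for that loss. With quantile normalization and an estimated correlation, the heat shock (adjusted p = 0.044), replication (0.044) and MYC (0.038) lists passed. With scaling to the detected probes these passed too (adjusted p = 0.032, 0.032 and 0.019 with an estimated correlation), as did the interferon list (0.037). Over the alternatives, adjusted p-values with an estimated correlation were 0.032 to 0.99 for heat shock, 0.032 to 0.99 for replication, 0.019 to 0.99 for MYC, 0.037 to 0.99 for interferon and 0.18 to 0.99 for the T-cell list. For each of the 5, the medians of all 3 TAS-116 arrays lay on the same side of those of all 3 DMSO arrays. The same held for lists without a call, such as the chaperonin and JAK-STAT lists, so it does not set the 5 apart. With the preset correlation, adjusted p-values over the alternatives were 5.0e-93 to 4.7e-21 for the replication list, 1.1e-30 to 2.3e-14 for the MYC list, 2.0e-17 to 2.0e-08 for the heat shock list and 6.5e-11 to 6.5e-06 for the interferon list. The self-contained test fry called 22 of the 30 lists in 1 direction and all 30 in either direction, without comparing a list with other genes. For 22 of the 30 lists the counts of passing genes were the same adjusted over the list alone, and the exceptions are given beside their lists. Names in brackets after a count are the members that rose or fell, and those outside the rule for naming genes were chosen after their values were seen.

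**Figure D1:**
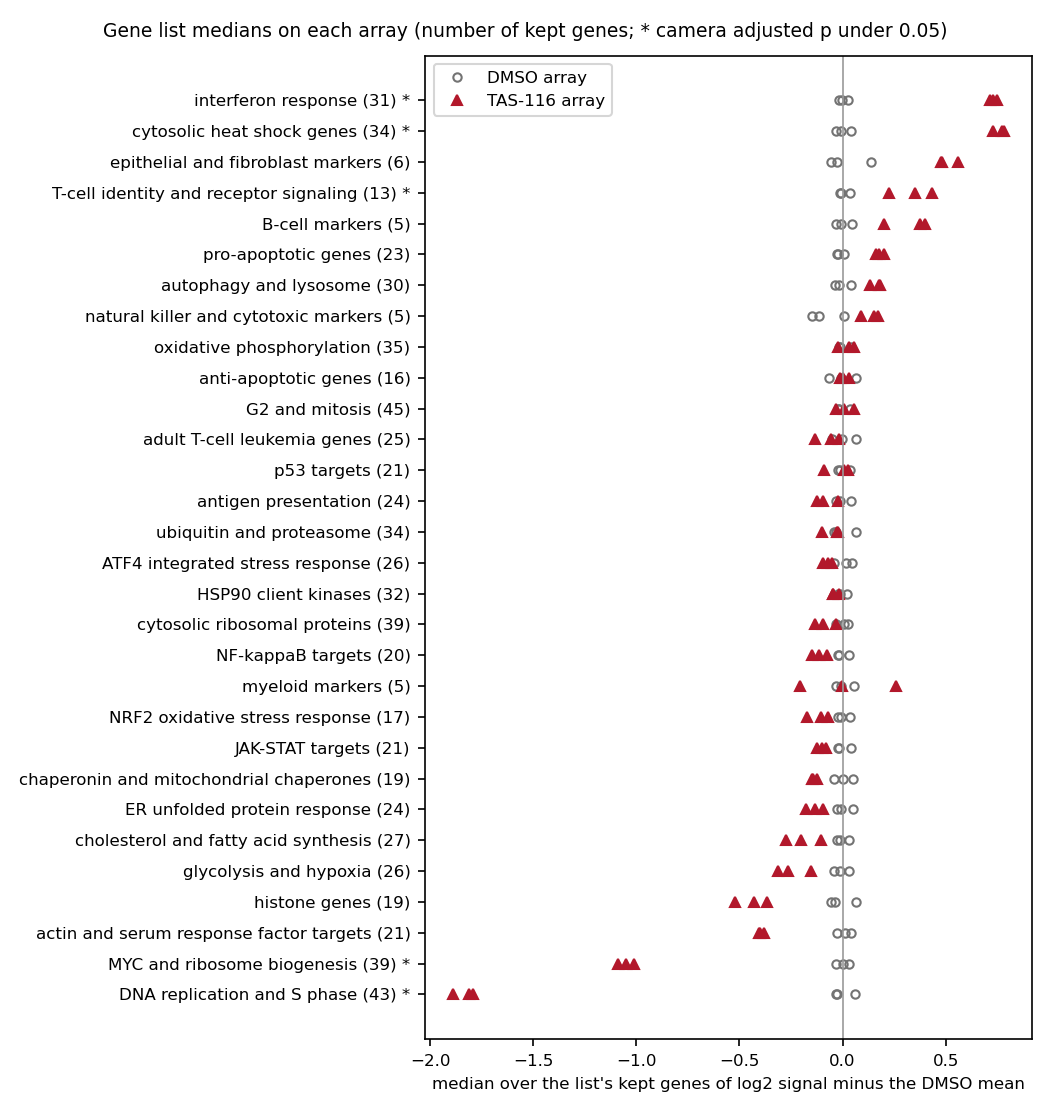
Median log2 signal, relative to the DMSO mean, over the kept genes of each of the 30 lists on each array; circles are DMSO arrays, triangles are TAS-116 arrays, the number of genes is in brackets and an asterisk marks a camera adjusted p under 0.05. The 3 TAS-116 arrays lie between -1.89 and -1.79 for DNA replication, between -1.09 and -1.01 for MYC and ribosome biogenesis, and between 0.71 and 0.78 for the interferon and heat shock lists.

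Cytosolic heat shock genes, the targets of the transcription factor HSF1, rose almost as a group. Of 34 members measured, 30 rose, 2 fell (IER5 and BAG1) and 2 did not pass the test. Their median log2 fold change was 0.76 (camera adjusted p = 3.1e-10, and adjusted p = 0.23 with an estimated correlation), and 0.78 within slide 1. HSPA1A had the largest rise of these, from 6.78 ± 0.042 in DMSO to 8.98 ± 0.035 in TAS-116 (log2 signal relative to the array's 75th percentile, mean ± SD, n = 3 each). Its log2 fold change was 2.20 ± 0.054 (SE), with an adjusted p of 2.7e-06, and 2.21 within slide 1. HSPA1B, a near-identical copy, had a log2 fold change of 1.99 ± 0.069, and the probes of the pair can cross-hybridise, so their separate changes are uncertain. CLU, which encodes the extracellular chaperone clusterin, rose by 2.01 ± 0.085 on the log2 scale. The HSPA1A probe lies on chromosome 6, 31785491 to 31785550, the HSPA1B probe on chromosome 6, 31797870 to 31797929 and the CLU probe on chromosome 8, 27457403 to 27457462, in hg19 as the array files give it. The HSP90 genes themselves moved less than HSPA1A, HSPA1B and CLU. HSP90AB1, the constitutive beta form, rose by 0.75 ± 0.070 (adjusted p = 0.00015). HSP90AA1, the inducible alpha form, rose by 0.30 ± 0.065 (adjusted p = 0.0069), and its call was lost within slide 1 (log2 fold change 0.26, adjusted p = 0.077, and 1.1e-05 to 0.20 over its alternatives). This gene's brightest probe showed the smallest change of its 3 kept probes, which ranged from 0.30 to 1.12. HSF1 was lower, with a log2 fold change of -0.47 ± 0.064 (adjusted p = 0.00083). HSP90B1, the endoplasmic reticulum form, had a log2 fold change of -0.15 ± 0.057 and missed the threshold (adjusted p = 0.066), and quantile normalization turned its value to 0.020. It passed as lower with median scaling (adjusted p = 0.037), slide as a random block (0.037) or limma's trend and robust options (0.021), with adjusted p-values of 0.021 to 0.81 over its alternatives.

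Other proteostasis lists did not shift by camera. Among 19 chaperonin and mitochondrial chaperone genes, 2 rose (HSPE1 and TCP1), 9 fell and 8 did not pass the test (median -0.13, camera adjusted p = 0.22, -0.13 within slide 1, but 0.043 with quantile normalization). The list was called lower with no filter on dim probes (adjusted p = 0.036, and 0.036 to 0.71 over its alternatives), but not with an estimated correlation (adjusted p = 0.75). TRAP1, the mitochondrial HSP90, was 2.45-fold lower (log2 fold change -1.29 ± 0.077, adjusted p = 2.5e-05), and GRPEL1 and DNAJA3, co-chaperones of mitochondrial HSP70, had log2 fold changes of -1.04 and -0.75. Of 34 ubiquitin and proteasome genes, 4 rose, 11 fell and 19 did not pass the test (median -0.056, camera adjusted p = 0.53, -0.026 within slide 1, but 0.11 with quantile normalization, 0.064 with scaling to the detected probes and 0.0032 with DMSO replicate 2 left out). The falls were small, -0.51 for PSMD7, -0.50 for PSMD14 and -0.43 for PSMD12, all subunits of the proteasome's regulatory particle. Of 24 genes listed for the unfolded protein response of the endoplasmic reticulum, 5 rose (CRELD1, SEL1L, SYVN1, EDEM1 and WFS1), 10 fell and 9 did not pass the test (median -0.14, camera adjusted p = 0.57, -0.096 within slide 1). MANF and SDF2L1, secreted and luminal proteins induced by misfolded proteins, fell with log2 fold changes of -1.0 and -0.85. The listed gene CRELD1 rose by 0.80, but whether it takes part in this response was not tested.

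DNA replication and S-phase genes fell without exception among those measured. All 43 of 43 genes passed the test, 40 of them by at least 2-fold, with a median log2 fold change of -1.82 (camera adjusted p = 9.2e-23, and adjusted p = 0.23 with an estimated correlation) and -1.79 within slide 1. CCNE2 fell from 2.27 ± 0.076 to -1.37 ± 0.13, a log2 fold change of -3.64 ± 0.084 (adjusted p = 2.5e-06, -3.55 within slide 1), measured by a probe on chromosome 8, 95892618 to 95892677 (hg19). RRM2, the inducible subunit of ribonucleotide reductase, was 6.47-fold lower. CDC6, which loads the replicative helicase, was not well above background on any TAS-116 array and was at least 4.55-fold lower (adjusted p = 2.9e-05), but its log2 fold change with normexp background, whose offset compresses low signals, was -1.28. The list of G2 and mitosis genes did not shift. Of its 45 genes, 12 rose, 13 fell and 20 did not pass the test (median 0.0046, mean -0.055, camera adjusted p = 0.94, 0.056 within slide 1, but -0.047 with median scaling, -0.0049 with normexp background, -0.052 with E1A scaling, -0.0052 with slide as a random block, -0.020 with DMSO replicate 3 left out, -0.018 with TAS-116 replicate 1 left out and -0.021 with TAS-116 replicate 3 left out). CENPM, a centromere protein, AURKB, the kinase of the chromosomal passenger complex, and MYBL2, a transcription factor of the cell cycle, fell with log2 fold changes of -1.10, -0.96 and -0.91. The 3 kept probes of CENPM ranged from -1.84 to -1.08. Of 19 histone genes, 4 rose (H2AC6, H2BC12, H2AC25 and H2BC5), 12 fell and 3 did not pass the test (median -0.39, camera adjusted p = 0.077, -0.37 within slide 1). The list was called lower with no filter on dim probes, slide as a random block or scaling to the detected probes (adjusted p of 0.0083 to 0.11 over its alternatives). With an estimated correlation it was not called in these settings (adjusted p = 0.75, 0.87 and 0.35). The linker histone genes H1-5 and H1-3 fell, with log2 fold changes of -2.31 ± 0.094 and -1.92 ± 0.075. H2AC6 rose by 2.16 ± 0.075 on its brightest probe, but its 3 kept probes disagreed, from -0.51 to 2.16, so its direction is open.

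Among 21 targets of the tumor suppressor p53, 8 rose, 8 fell and 5 did not pass the test (median -0.045, mean -0.13, camera upward with an adjusted p of 0.92, 0.0090 within slide 1, but 0.10 with quantile normalization and 0.075 with scaling to the detected probes). PLK3, a stress-responsive kinase, and AEN, an apoptosis-enhancing nuclease, fell with log2 fold changes of -1.67 ± 0.094 and -1.52 ± 0.056. CDKN1A, the cyclin-dependent kinase inhibitor p21, was not well above background on any TAS-116 array and was at least 2.03-fold lower (adjusted p = 0.049), but had a log2 fold change of -0.48 with normexp background. That call was lost in several alternatives, among them the fits without DMSO replicate 1 (adjusted p = 0.10), 2 (0.13) or 3 (0.085) or without TAS-116 replicate 2 (0.098), and adjusted p-values over its alternatives ranged, with 0.0015 within slide 1, from 1.7e-05 to 0.19.

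**Figure D2:**
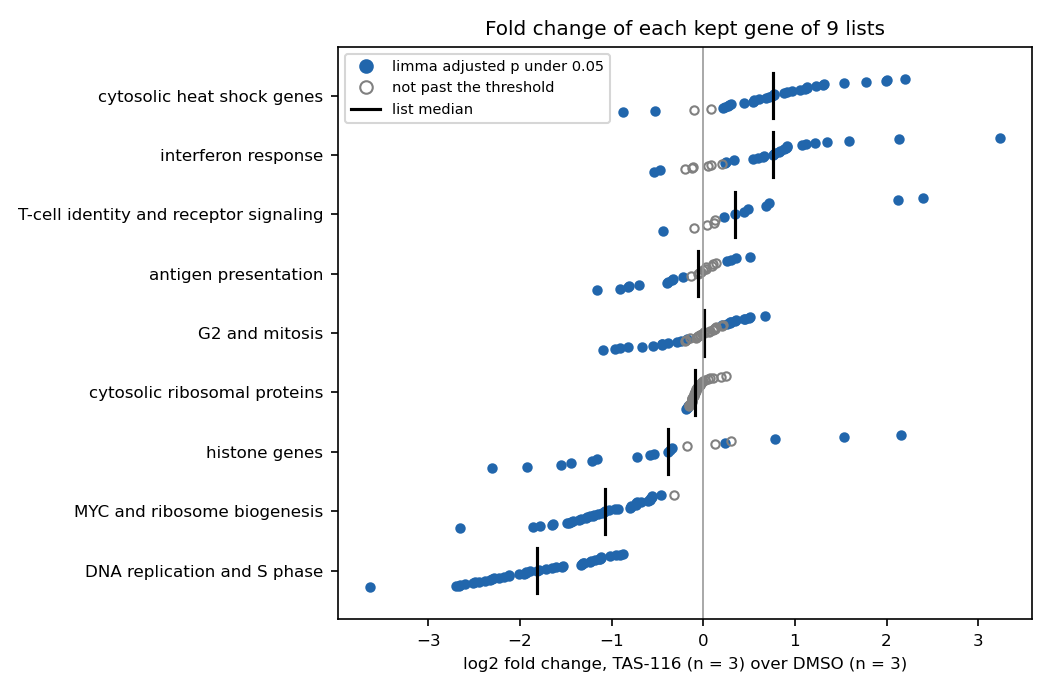
Log2 fold change of each kept gene of 9 lists, TAS-116 (n = 3) over DMSO (n = 3); filled points passed limma's threshold, open points did not, and black bars are list medians. All 43 replication genes lie below 0, while the 45 G2 and mitosis genes lie on both sides of it.

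MYC and the ribosome biogenesis genes it drives were lower. Of 39 genes on the list, none rose and 38 fell, 21 of them by at least 2-fold, and adjusted over the list alone all 39 fell. The exception by limma was NPM1, with a log2 fold change of -0.32 (adjusted p = 0.055). The median log2 fold change was -1.07 (camera adjusted p = 8.6e-16, and adjusted p = 0.23 with an estimated correlation) and -1.05 within slide 1. MYC fell from 6.0 ± 0.052 to 3.34 ± 0.051, a log2 fold change of -2.66 ± 0.058 (adjusted p = 2.3e-06, -2.61 within slide 1), on a probe at chromosome 8, 128753268 to 128753327 (hg19). BOP1, a factor for the maturation of the large ribosomal subunit, and CAD, the enzyme that starts pyrimidine synthesis, were 3.64-fold and 3.45-fold lower. Few structural genes of the cytosolic ribosome passed the test. Of 39 genes, 0 rose and 4 fell (RPL8, RPL35, RPL10A and RPL13) by limma, and adjusted over the list alone none passed. The median was -0.087 (camera adjusted p = 0.27, -0.096 within slide 1, but 0.033 with scaling to the detected probes). RPL13, RPL10A and RPL35 had log2 fold changes of -0.19, -0.18 and -0.17, and all 3 calls were lost within slide 1, where TAS-116 had 1 array and the values were -0.17, -0.21 and -0.16. The 2 kept probes of RPL13 gave log2 fold changes of -0.64 and -0.19, and both passed the threshold. Over the alternatives, adjusted p-values were 0.00095 to 0.28 for RPL13, 0.0055 to 0.38 for RPL10A and 0.0051 to 0.40 for RPL35. The call of RPL13 was also lost without DMSO replicate 2 (0.086), DMSO replicate 3 (0.071), TAS-116 replicate 1 (0.073) and TAS-116 replicate 2 (0.099). For RPL10A this held without DMSO replicate 2 (0.079), DMSO replicate 3 (0.098), TAS-116 replicate 1 (0.11) and TAS-116 replicate 2 (0.095). For RPL35 it held without DMSO replicate 2 (0.064), DMSO replicate 3 (0.067), TAS-116 replicate 1 (0.074), TAS-116 replicate 2 (0.080) and TAS-116 replicate 3 (0.060).

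Lists of metabolism and of metabolic stress did not shift by camera, although single genes changed strongly. Of 26 glycolysis and hypoxia genes, 5 rose (NDRG1, SLC2A3, P4HA1, ALDOC and PFKFB4), 13 fell and 8 did not pass the test (median -0.22, camera adjusted p = 0.22, -0.27 within slide 1), and adjusted over the list alone 5 rose and 15 fell. HK2, the hexokinase typical of proliferating cells, was 3.46-fold lower, and NDRG1, a hypoxia-induced gene, was 2.41-fold higher. The glucose transporter gene SLC2A3 was not well above background on any DMSO array and was at least 1.53-fold higher (adjusted p = 0.014), but had a log2 fold change of 0.32 with normexp background. Its call was lost within slide 1 (log2 fold change 0.99 against 1.16 over all 6 arrays, adjusted p = 0.14, and 7.7e-05 to 0.14 over its alternatives). Of 27 cholesterol and fatty acid synthesis genes, 7 rose, 13 fell and 7 did not pass the test (median -0.19, camera adjusted p = 0.36, -0.20 within slide 1), or 8 and 15 adjusted over the list alone. HMGCS1, of the mevalonate pathway, rose by 0.89. SREBF1, the transcription factor of lipid synthesis, and ACACA, which makes malonyl-CoA, had log2 fold changes of -0.81 and -0.75. The 2 kept probes of SREBF1 gave -0.81 and -0.31. Of 35 oxidative phosphorylation genes, 3 rose (NDUFB5, SDHC and UQCRC2), 5 fell (COX5A, SDHA, CYC1, UQCRFS1 and NDUFB10) and 27 did not pass the test (median 0.010, mean -0.0067, camera adjusted p = 0.92, 0.029 within slide 1, but -0.041 with median scaling, -0.047 with E1A scaling, -0.0044 with slide as a random block, -0.0026 with TAS-116 replicate 1 left out and -0.0038 with TAS-116 replicate 3 left out), or 2 and 5 adjusted over the list alone. The complex I gene NDUFB10 and the complex III gene UQCRFS1 had log2 fold changes of -0.43 and -0.31, and NDUFB5 rose by 0.33, a call that was lost within slide 1 (log2 fold change 0.30, adjusted p = 0.21, and 0.0027 to 0.21 over its alternatives) and without TAS-116 replicate 1 (0.055), TAS-116 replicate 2 (0.084) and TAS-116 replicate 3 (0.052). The oxidative phosphorylation list was called higher with quantile normalization (adjusted p = 0.033, and 0.033 to 0.99 over its alternatives), but not with an estimated correlation (adjusted p = 0.18). Among 26 genes of the ATF4 integrated stress response, 9 rose, 10 fell and 7 did not pass the test (median -0.060, mean 0.048, camera upward with an adjusted p of 0.94, -0.071 within slide 1, but 0.13 with quantile normalization and 0.060 with scaling to the detected probes). DDIT4, an inhibitor of mTORC1, was 3.51-fold and SLC7A11, the cystine transporter, 2.35-fold higher, and SLC7A1, an arginine transporter, was 2.33-fold lower. Among 17 genes of the NRF2 oxidative stress response, 4 rose (OSGIN1, SLC7A11, FTL and PRDX1), 6 fell and 7 did not pass the test (median -0.12, camera adjusted p = 0.61, -0.073 within slide 1, but 0.046 with quantile normalization). OSGIN1, measured above background on 1 of 3 DMSO arrays, had a log2 fold change of 1.33 ± 0.30 (0.55 with normexp background), and TXNRD1, thioredoxin reductase, one of -0.92.

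Interferon-response genes were higher with TAS-116. Of 31 measured, 23 rose, 2 fell (PARP9 and HERC5) and 6 did not pass the test, and adjusted over the list alone 24 rose and 2 fell. Their median log2 fold change was 0.77 (camera adjusted p = 4.2e-07, and adjusted p = 0.23 with an estimated correlation), and 0.71 within slide 1. ISG20 rose from 3.80 ± 0.11 to 5.94 ± 0.027, a log2 fold change of 2.14 ± 0.069 (adjusted p = 3.7e-06, 2.11 within slide 1), on a probe at chromosome 15, 89198784 to 89198843 (hg19). IFI44, an interferon-induced protein gene, was 3-fold higher. Its neighbour IFI44L, which was well above background on 2 of 3 DMSO arrays, had a log2 fold change of 3.24 ± 0.34 (adjusted p = 0.00025), lowered to 1.93 by normexp background. HERC5 and PARP9 had log2 fold changes of -0.53 and -0.48. Antigen presentation genes did not shift by camera. Of 24 such genes, 4 rose (ERAP2, HLA-DMA, HLA-DPA1 and HLA-DPB1), 10 fell and 10 did not pass the test (median -0.053, camera adjusted p = 0.32, -0.093 within slide 1, but 0.067 with scaling to the detected probes). CIITA, the activator of MHC class II genes, was 2.23-fold lower. The class II genes did not move together. HLA-DRA was 1.88-fold lower, while HLA-DMA, HLA-DPA1 and HLA-DPB1 rose. TAP1, the peptide transporter of MHC class I loading, was 1.77-fold lower.

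Genes of T-cell identity and receptor signaling were higher, although only 13 of the 36 listed were bright enough to be kept. Of these, 8 rose, 1 fell (TBX21) and 4 did not pass the test, with a median log2 fold change of 0.35 (camera adjusted p = 0.024, and adjusted p = 0.23 with an estimated correlation) and 0.43 within slide 1. The call was lost without TAS-116 replicate 1 (adjusted p = 0.054) and with only genes above background on all 6 arrays (adjusted p = 0.060), and adjusted p-values over its alternatives ranged from 0.0071 to 0.060. With no filter on dim probes the list's median was 0.026. FYN, a SRC-family kinase, was 1.64-fold higher. CXCR3, a chemokine receptor, was 4.35-fold higher on its brightest probe, but its 2 kept probes gave log2 fold changes of 0.64 and 2.12. The adhesion molecule gene CD2, above background on 1 of 3 DMSO arrays, had a log2 fold change of 2.39 ± 0.17 (adjusted p = 5.3e-05), lowered to 1.19 by normexp background. Of 25 genes tied to adult T-cell leukemia, 6 rose, 11 fell and 8 did not pass the test (median -0.021, camera adjusted p = 0.63, -0.055 within slide 1, but 0.079 with quantile normalization, 0.099 with scaling to the detected probes and 0.035 with TAS-116 replicate 2 left out). EPAS1, encoding HIF-2 alpha, was 3.35-fold higher. HBEGF, a growth factor gene, was not well above background on any DMSO array and was at least 2.10-fold higher (adjusted p = 0.00039), but had a log2 fold change of 0.79 with normexp background.

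Signaling lists held more falls than rises but did not shift by camera. Of 20 NF-kappaB targets, 2 rose (NFKB2 and REL), 9 fell and 9 did not pass the test (median -0.098, camera adjusted p = 0.38, -0.15 within slide 1, but 0.047 with quantile normalization, 0.022 with scaling to the detected probes and 0.019 with the median of probes). NFKBIA, the inhibitor that NF-kappaB itself induces, IER3 and CD83 had log2 fold changes of -0.90, -0.88 and -0.75. Of 21 JAK-STAT targets, 1 rose (JAK1), 9 fell and 11 did not pass the test (median -0.13, camera adjusted p = 0.31, -0.079 within slide 1), and MYC is on this list too. SOCS3, a feedback inhibitor of cytokine signaling, and the cytokine gene OSM had log2 fold changes of -1.38 and -1.34. The 2 kept probes of OSM gave -1.34 and -0.84. Of 21 actin and serum response factor targets, 5 rose (FOSB, DUSP5, CNN2, TPM1 and VCL), 13 fell and 3 did not pass the test (median -0.45, camera adjusted p = 0.077, -0.40 within slide 1). The list was called lower with quantile normalization, no filter on dim probes or scaling to the detected probes (adjusted p of 0.034 to 0.11 over its alternatives). With an estimated correlation it was not called in these settings (adjusted p = 0.22, 0.66 and 0.23). DUSP2, a phosphatase of MAP kinases, was not well above background on any TAS-116 array and was at least 7.53-fold lower (adjusted p = 8.5e-05), but had a log2 fold change of -1.62 with normexp background. JUN, a subunit of AP-1, was 4.44-fold lower and DUSP6, a phosphatase of ERK, 2.79-fold lower (log2 fold change -1.48, but -0.81 with normexp background). Genes of the kinases known as HSP90 clients, whose proteins rather than transcripts depend on the chaperone, went both ways. Of 32, 8 rose, 11 fell and 13 did not pass the test (median -0.061, camera adjusted p = 0.82, -0.018 within slide 1, but 0.016 with quantile normalization and 0.059 with scaling to the detected probes). CHEK1, the replication checkpoint kinase, CDK2 and CDK4 were 3.45-fold, 2.23-fold and 2.01-fold lower.

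Cell death and autophagy lists did not shift by camera either. Of 23 pro-apoptotic genes, 9 rose, 6 fell and 8 did not pass the test (median 0.20, camera adjusted p = 0.41, 0.17 within slide 1), and adjusted over the list alone 11 rose and 6 fell. TNFRSF10A, a receptor for TRAIL, and CASP2, a caspase, had log2 fold changes of -0.97 and -0.73. The 2 kept probes of CASP2 gave -0.73 and -0.23, and only 1 passed the test. CYCS, encoding cytochrome c, had a log2 fold change of -0.74, and its 3 kept probes disagreed, from -0.77 to 0.34. Of 16 anti-apoptotic genes, 2 rose (MCL1 and BIRC6), 4 fell (BIRC5, BCL2L2, TRAF2 and PIM3) and 10 did not pass the test (median 0.010, mean -0.078, camera downward with an adjusted p of 0.94, 0.0030 within slide 1, but -0.041 with median scaling, -0.047 with E1A scaling, -0.031 with the median of probes, -0.036 with DMSO replicate 1 left out and -0.0048 with TAS-116 replicate 2 left out), and 3 fell adjusted over the list alone. PIM3, a survival kinase, and TRAF2, an adaptor of TNF receptors, had log2 fold changes of -0.88 and -0.57, and BCL2L2, above background on 2 of 3 TAS-116 arrays, one of -0.55. Of 30 autophagy and lysosome genes, 13 rose, 5 fell and 12 did not pass the test (median 0.16, camera adjusted p = 0.077, 0.18 within slide 1). The list was called higher with quantile normalization, no filter on dim probes, the median of probes or scaling to the detected probes (adjusted p of 0.012 to 0.15 over its alternatives). With an estimated correlation it was not called in these settings (adjusted p = 0.31, 0.75, 0.75 and 0.27). WIPI1, of the autophagosome membrane, OPTN, an autophagy receptor, and CTSB, a lysosomal protease, rose by 0.94, 0.89 and 0.69 on the log2 scale.

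Most markers of other cell types were too dim to be kept. Of 14 B-cell markers 5 were kept, of which 3 rose and 0 fell (median 0.32, camera adjusted p = 0.26, 0.20 within slide 1, and 0.025 with no filter on dim probes). EBF1, BLK and VPREB3 had log2 fold changes of 0.80, 0.66 and 0.32, the last without a call within slide 1 (log2 fold change 0.20, adjusted p = 0.21, and 0.0026 to 0.21 over its alternatives). The 2 kept probes of EBF1 gave log2 fold changes of 0.38 and 0.80, and only 1 passed the test. Of 18 myeloid markers 5 were kept, and 1 rose (median -0.12, mean 0.038, camera upward with an adjusted p of 0.94, -0.21 within slide 1, but 0.00052 with scaling to the detected probes and 0.026 with TAS-116 replicate 2 left out). That gene, CD14, had a log2 fold change of 0.34 and lost its call within slide 1 (log2 fold change 0.36, adjusted p = 0.13, and 0.0028 to 0.16 over its alternatives), and FCER1G, with -0.19, missed the threshold (adjusted p = 0.060, and 0.019 to 0.43 over its alternatives), which it passed without DMSO replicate 1 (0.038) and TAS-116 replicate 2 (0.046) and with median scaling (0.040), normexp background (0.019), limma's trend and robust options (0.031) and slide as a random block (0.042). Of 17 natural killer and cytotoxic markers 5 were kept, of which 2 rose and 1 fell (median 0.14, camera adjusted p = 0.71, 0.17 within slide 1, but -0.084 with only genes above background on all 6 arrays). The granule gene GZMK rose by 0.67, NKG7, above background on 2 of 3 DMSO arrays, by 1.03 (0.43 with normexp background), and GZMB had a log2 fold change of -0.36, with the calls of NKG7 and GZMB lost within slide 1 (log2 fold change 0.84, adjusted p = 0.093, and 9.4e-06 to 0.093 over its alternatives, for NKG7, and log2 fold change -0.38, adjusted p = 0.13, and 0.0018 to 0.13 over its alternatives, for GZMB). GZMB also lost it without DMSO replicate 2 (0.059), DMSO replicate 3 (0.058), TAS-116 replicate 1 (0.055) and TAS-116 replicate 2 (0.063). Of 18 epithelial and fibroblast markers 6 were kept, of which 4 rose (COL1A1, EPCAM, ACTA2 and KRT8) and 1 fell (VIM) (median 0.54, camera adjusted p = 0.32, 0.48 within slide 1, but -0.024 with no filter on dim probes). COL1A1, a collagen gene, was 4.49-fold higher, EPCAM 1.81-fold and ACTA2 1.67-fold.

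Outside the lists, the largest changes among named genes measured on all 6 arrays were falls of 13-fold for CDCA7 (on its brightest probe) and 12.7-fold for FAM111B and a rise of 11.5-fold for GPR171. GPR171, a G-protein-coupled receptor gene, rose from -2.34 ± 0.12 to 1.19 ± 0.051, a log2 fold change of 3.52 ± 0.074 (adjusted p = 2.3e-06, 3.58 within slide 1), at chromosome 3, 150916287 to 150916346 (hg19). RIPOR2, a gene of T-cell polarity and migration, and RAB37, a small GTPase of secretion, rose 6.63-fold and 6.59-fold on their brightest probes. The 2 kept probes gave log2 fold changes of 1.76 and 2.73 for RIPOR2 and of 1.71 and 2.72 for RAB37. The glutamate receptor gene GRM4, the phosphatase pseudogene PTPRVP and the galectin gene LGALS9C rose 6.09-fold, 5.89-fold and 5.40-fold. Normexp background, whose offset compresses low signals, brought the log2 fold changes closer to 0, to 2.70 for GPR171, 2.02 for RIPOR2, 1.83 for RAB37, 1.57 for GRM4, 1.43 for PTPRVP and -2.21 for PAQR4. LGALS9C has near-identical copies whose transcripts its probe can also capture. CDCA7, a chromatin factor of cycling cells, had a log2 fold change of -3.70 ± 0.089 (adjusted p = 2.6e-06, -3.69 within slide 1), at chromosome 2, 174233490 to 174233549 (hg19), but its 2 kept probes gave -3.70 and -2.07. FAM111B had one of -3.66 ± 0.11 (-3.82 within slide 1). ID1, an inhibitor of helix-loop-helix transcription factors, was 10.8-fold lower (2.73 ± 0.043 in DMSO and -0.69 ± 0.075 in TAS-116). DTL, which marks replication proteins for degradation, and PAQR4 were 8.27-fold and 7.92-fold lower. Of the 102 genes named by the fixed rule, which mostly takes genes past the threshold, 100 passed it. The groups of these genes did not overlap, so all 100 had to keep their direction within slide 1. There, 10 of them lost the call, which were RPL13, RPL10A, RPL35, SLC2A3, NDUFB5, VPREB3, CD14, NKG7, GZMB and HSP90AA1, in a fit with 1 TAS-116 array.

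**Figure D3:**
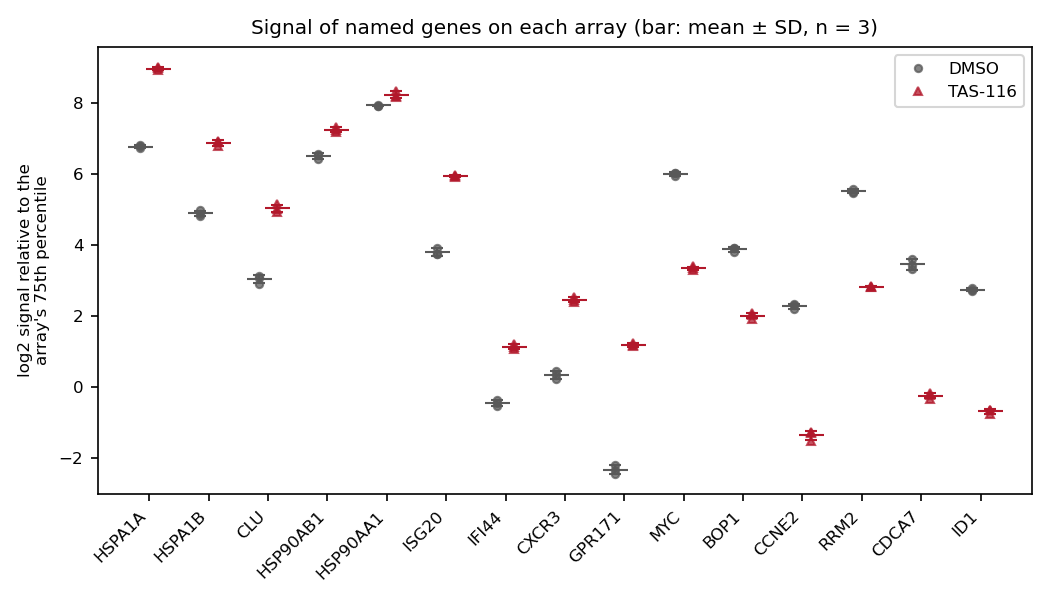
Log2 signal relative to the array's 75th percentile for 15 named genes on each of the 6 arrays, with the mean and SD of each group (n = 3). HSPA1A rises from 6.78 to 8.98, CCNE2 falls from 2.27 to -1.37, and the level of one gene's probe cannot be set against that of another.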

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

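The 2 scalings named as chosen after seeing the data were added later, and the others were planned. The heat shock list stayed higher and past the threshold under each alternative run with the preset correlation, with a median of 0.70 to 0.89. Over the 6 fits that leave out 1 sample, genes higher ranged from 3677 to 3980 and genes lower from 4309 to 4578. Against 4244 genes higher, no filter on dim probes gave 2748 (with 36323 genes tested), slide as a block 2827, slide 1 alone 2464 (with 4 arrays) and E1A scaling 2504. Against 4793 genes lower, slide 1 alone gave 3116. Against 552 genes higher by at least 2-fold, normexp, whose offset of 50 compresses low signals, gave 197, and genes above background on all 6 arrays 356. Against 3 lists higher, quantile normalization gave 5 and an estimated correlation 0. Against 2 lists lower, no filter on dim probes gave 5, the percentile over detected probes 4 and an estimated correlation 0. An estimated correlation gave 1 list higher and 2 lower with quantile normalization, 2 and 2 with the percentile over detected probes, and 0 under the other alternatives run with it. Where no construction is named, the cause was not tested. With the replicate number as a replicate block, 3869 genes were higher and 4416 lower, and no list call changed. Deviations of same-numbered arrays from their group means correlated across genes at -0.042, -0.0062 and -0.11, so no pairing by number was visible. This does not tell whether same-numbered samples were handled together. Over 21 alternatives for single lists, 616 of 630 comparisons kept the side of the threshold, 12 gained a call and 2 lost it, and none of the 5 called lists changed direction. Of 2132 comparisons of single named genes, 82 lost the call, in 13 genes (the 10 that lost it within slide 1, CDKN1A, and, with no filter on dim probes, OSGIN1 with an adjusted p of 0.054, and 1.0e-05 to 0.054 over its alternatives, and UQCRFS1 with 0.057, and 8.2e-05 to 0.057 over its alternatives), 9 gained it and 1 turned round. This was H2AC6, which had -0.51 with the median over its probes, since those disagree. Leaving out saturated probes removed none. Signal over background limits the dim genes. With no filter on dim probes, 5585 of the 9037 calls were kept. The called genes had the same probes and values there. Their losses therefore came with the genes added to the fit and its adjustment, and do not show that the lost genes were dim.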

Other observations

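Tests chosen only after the result was seen were those of the slide, of the antigen presentation list, of uniform slowing of the cycle and of other splits of the samples, as were the 7 lists of the next paragraph, whose shifts were then predicted before they were computed.

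Further growth-related gene groups were lower with TAS-116. Among homologous recombination and Fanconi anemia genes, 28 of 30 genes fell and 0 rose (median -0.85, camera adjusted p = 5.1e-11, adjusted p = 0.19 with an estimated correlation), with a log2 fold change of -1.92 for XRCC2, a recombination factor. Of purine and pyrimidine synthesis genes, 20 of 22 genes fell and 0 rose (median -0.90, camera adjusted p = 3.2e-08, adjusted p = 0.19 with an estimated correlation), with -1.52 for CTPS1, CTP synthase, and -1.42 for PPAT, the first enzyme of purine synthesis. Of nuclear pore and import genes, 25 of 30 genes fell and 0 rose (median -0.45, camera adjusted p = 1.2e-06, adjusted p = 0.19 with an estimated correlation), RCC1, the exchange factor of RAN, at -1.41. Smaller shifts were measured for the spliceosome, where 25 of 36 genes fell and 3 rose (median -0.30, camera adjusted p = 4.2e-05, adjusted p = 0.19 with an estimated correlation), and for chromatin remodelling and heterochromatin genes, where 17 of 30 genes fell and 7 rose (median -0.26, camera adjusted p = 0.0496, adjusted p = 0.41 with an estimated correlation). SUV39H2, a histone methyltransferase, had a log2 fold change of -1.40, and CHD3, a remodelling helicase, one of 0.92. All 5 of these predictions of a fall were met. Mitochondrial ribosomal protein genes were predicted to fall, and 40 of 75 genes fell and 2 rose (median -0.199, camera adjusted p = 4.2e-05, adjusted p = 0.32 with an estimated correlation), a median just short of the -0.2 set beforehand. Genes of transport from the endoplasmic reticulum to the Golgi were predicted to stay in place. Their median stayed within 0.2 of 0, but 13 of 31 genes rose and 2 fell, and camera called the list higher (median 0.18, camera adjusted p = 0.0069, adjusted p = 0.26 with an estimated correlation), COPA, a subunit of the COPI coat, at 0.99. The lists were written after the changes of single genes had been seen, so they are not independent evidence, and the adjustment covers these 7 lists.

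Of 31 interferon-response genes 23 rose and 2 fell, and camera's call of the list had an adjusted p = 0.23 with an estimated correlation (0.037 with scaling to the detected probes). The list's median was 0.71 on the 1 TAS-116 array of slide 1, which also held all DMSO arrays. The rise was thus present within a slide, but 1 array cannot settle whether slides or scans contributed. The values argue against noise of dim probes, since over the 28 members well above background on all 6 arrays the median was 0.70 ± 0.035 (mean and SD of the 3 TAS-116 arrays). The antigen presentation list's median was -0.080 ± 0.053, against 0.73 for the interferon list. The difference exceeded the SD of 0.43 between the antigen presentation genes. This test was chosen after the result was seen, so it restates the pattern. The antigen presentation list holds class II genes and their activator CIITA beside TAP1 of class I loading. Its median thus does not isolate interferon-induced genes and cannot decide on a general interferon response that includes the antigen-presentation targets. A response to TAS-116 limited to part of the interferon-regulated genes stays open as a hypothesis, and neither interferon secretion nor STAT activation was measured.

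All 43 replication genes kept fell while the mitosis list did not shift, and the replication call had an adjusted p = 0.23 with an estimated correlation (0.032 with scaling to the detected probes). The replication median was -1.79 on the 1 TAS-116 array of slide 1, which also held all DMSO arrays. The fall was thus present within a slide, but 1 array cannot settle whether slides contributed. With scaling to the E1A controls the replication median was -1.88. This argues against the scaling between arrays as the source of the fall itself. Such a scaling moves all genes of an array alike. It could not change the gap between the replication and mitosis lists, so it is no test of that gap. The test of a uniform slowing, in which all cycle genes fall alike, used the mitosis median that is part of this pattern. It was 0.010 ± 0.045 over the 3 TAS-116 arrays, against -1.83 ± 0.052 for replication, with an SD of 0.41 between members. The lists thus did not fall alike, but this restates the pattern and is no separate evidence. A candidate explanation is a fall in the transcription of S-phase genes in cells that still pass through or wait in G2 and mitosis, which these arrays cannot show, since the shares of cells in each phase were not measured.

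The 6 arrays make only 10 splits into 3 and 3, too few for a share under 0.05. By limma, the real split gave 9037 genes past the threshold, which 1 of the 10 splits reached (the real one), and the highest of the other splits gave 0 (with at most 321 genes at an unadjusted p under 0.05, against 9879 for the real split). Each other split puts arrays of both groups on each side, so the difference between the groups adds to the spread there. Their counts therefore do not show what would be called without an effect.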
